A study of Mus musculus with 20 samples.

How the data were processed

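The series compares livers of diet-induced obesity responders and non-responders, 10 samples of each from male C57BL/6J mice, with 1 array per sample. RNA was labelled with Cy3 after linear amplification, per the labels' protocols. The labels give each array's group and a number, name no test, and do not state the feeding state or the hour of sampling.

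Each array was deposited as the scanner output of Agilent Feature Extraction. The version is 10.5.1.1 per the file headers and 9.1 per the submitters' processing notes, and which of them made the values is not settled. The deposited values are spot intensities on a linear scale. The processed intensity is background-subtracted and detrended within the array, per the file headers, and is not scaled between arrays. The authors' deposited table of processed intensity holds 33220 rows. Its sorted columns differ little from array to array, as quantile normalization would leave them, and 13013 rows repeat another row, of which 99.1% of the repeated sets name a single gene. How that table was made is not given in the sources used here. Its values are on a linear scale and not centred, and all 20 of its columns correlated best with their own array after each probe's mean was removed. Over genes with 1 probe, and without that removal, r with the own array lay between 0.996 and 0.999. The column medians of the table lay between 66.5 and 69.9.

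Each array held 45018 spots, of which 43379 were not controls, with 41174 different probes. The 75th percentile of processed signal was 280.1 to 417 in the first slide series and 413 to 657 in the second. The number of arrays limits the precision. Values were analysed as log2 of the processed signal minus each array's 75th percentile. Control spots and outlier-flagged spots were left out, and spots of a probe were averaged. Probes were kept if well above background on at least 5 arrays of either group, which left 26160. Each gene was represented by its brightest kept probe, and probes without a symbol were kept singly, which gave 17197 rows, 14512 of them with a gene symbol. Symbols came from the RefSeq gene table by accession for 27479 probes, by current symbol for 5478 and by older symbol for 679. The array's own symbol was kept for 788 probes, and 6750 had none. That table belongs to the assembly GRCm38.p6, and the positions of the array annotation to mm9, so it served for names only. Of the 27 named genes with several probes, the probes disagreed in sign for 2.

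Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with group and slide series as terms and Benjamini-Hochberg adjustment at 0.05. The slide series was read from the slide barcodes. It coincided with the scan date, so scan date as a block gives the same fit. The 20 arrays lay on 13 slides, 3 of which held both groups, and the correlation within slides was 0.0368. The first principal component held 35.7% of the variance, and slide series accounted for 42.9% of it. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. SEs of list means are over arrays. Igfbp2 and Dpp4 were also tested by permutation of the arrays. The same permutation test of Igfbp1 was added after its value was seen, and gave p = 0.00057.

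Genes were named by a rule written before the data were examined. It took, in each direction, up to 12 genes with the largest difference among those past the threshold and of the same sign in both slide series. As none passed, the genes with the smallest unadjusted p and the same sign in both series were named, leaving out predicted genes, clone names and accessions. It added Igfbp2 and Dpp4, the 4 leading members of each called list and up to 2 members of any other list that passed when adjusted over the list alone. Some genes that the rule names are not reported here, and no others were named in their place.

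The fit was tested on simulated data made from the real gene means and the shuffled deviations of the arrays. There were 200 changed genes in each of 10 simulations over 17197 genes. Changes of 0.5, 1 and 2 on the log2 scale were mixed within each simulation. A median of 2.5 unchanged genes were called. In a further simulation the bile acid list alone was shifted by 0.5, and the estimated-correlation test recovered it (adjusted p = 1.77e-09) with 0 other lists called, where the preset test called 12 others. The bile acid list has a low estimated correlation of 0.0213, against 0.385 for cell cycle genes and 0.404 for PPARA targets. Recovery of a shift in such correlated lists was not tested.

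Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, the authors' deposited values, 2 other filters on dim probes, no slide series term, a block on the number in the sample title, slide as a random block, each slide series alone, array weights, a trended robust variance, the mean of all probes of a gene, and all probes tested singly. Added after seeing the data were leaving out each array in turn, leaving out 3 arrays rich in pancreas or adipose markers, 2 clock components or Adipoq as covariates, and plain background subtraction.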

Results

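Liver RNA was profiled in 20 samples from male C57BL/6J mice, an inbred laboratory strain. The mice ate a diet with 60% of its calories from fat after weaning, and livers were taken at 6 weeks of age. The labels call 10 of them responders, meaning susceptible to diet-induced obesity, and 10 non-responders, meaning resistant. Each sample was hybridised to 1 single-colour Agilent array. The labels carry no animal identifiers, so the p-values measure the spread between these samples. Between 55.8% and 71.2% of the spots on an array were well above background, and no spot was saturated. The arrays came in 2 slide series, scanned on 2 dates. The first held 6 non-responders and 4 responders, and the second held 4 non-responders and 6 responders. All differences below are responder minus non-responder on the log2 scale, with the slide series as a term in the fit, and are given with their standard error (SE).

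The comparison asks which liver genes differ between mice that do and do not respond to the diet. The 2 genes chosen in advance were Igfbp2, which encodes a secreted binding protein of insulin-like growth factors, and Dpp4, which encodes a cell-surface peptidase that cleaves incretin hormones. Both were chosen because the laboratories behind the series had studied them in these or related mice, so they are not independent evidence. Igfbp2 signal was 5.69 ± 0.25 in responders and 6.14 ± 0.32 in non-responders, relative to each array's 75th percentile (SD, n = 10 each). The difference was -0.43 (SE 0.13), with a 95% interval of -0.70 to -0.16, and all 10 responders lay below the non-responder mean of their slide series. Dpp4 signal was 2.45 ± 0.16 in responders and 2.26 ± 0.17 in non-responders (SD, n = 10 each), a difference of 0.15 (SE 0.07), and all 10 responders lay above the non-responder mean of their series. The Igfbp2 difference was -0.52 in the first slide series and -0.34 in the second, and the Dpp4 difference was 0.10 and 0.20. With normexp background correction, whose fit failed on 6 arrays, 4 of them responders, the Igfbp2 difference was -0.98 (SE 0.37) and the Dpp4 difference turned to -0.15 (SE 0.23). The sign turns with normexp given below come from this same setting. Plain background subtraction with the same offset, added after seeing the data, turned none of them.

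Taken as single genes, both differences were larger than most chance assignments of arrays gave. A two-sided permutation test of the plain group means with 100000 resamples gave p = 0.00314 for Igfbp2 and p = 0.0226 for Dpp4. The exact permutation test within slide series, over 44100 arrangements, gave p = 0.00488 and p = 0.0312. Neither gene passed the adjustment over all genes, with limma adjusted p-values of 0.490 for Igfbp2 and 0.615 for Dpp4. The Igfbp2 probe lies on chromosome 1 from 72898677 to 72898736 and the Dpp4 probe on chromosome 2 from 62170062 to 62170121, in the mm9 coordinates of the array's annotation. Whether a probe falls in a coding exon or an untranslated region was not analysed here.

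**Figure D1:**
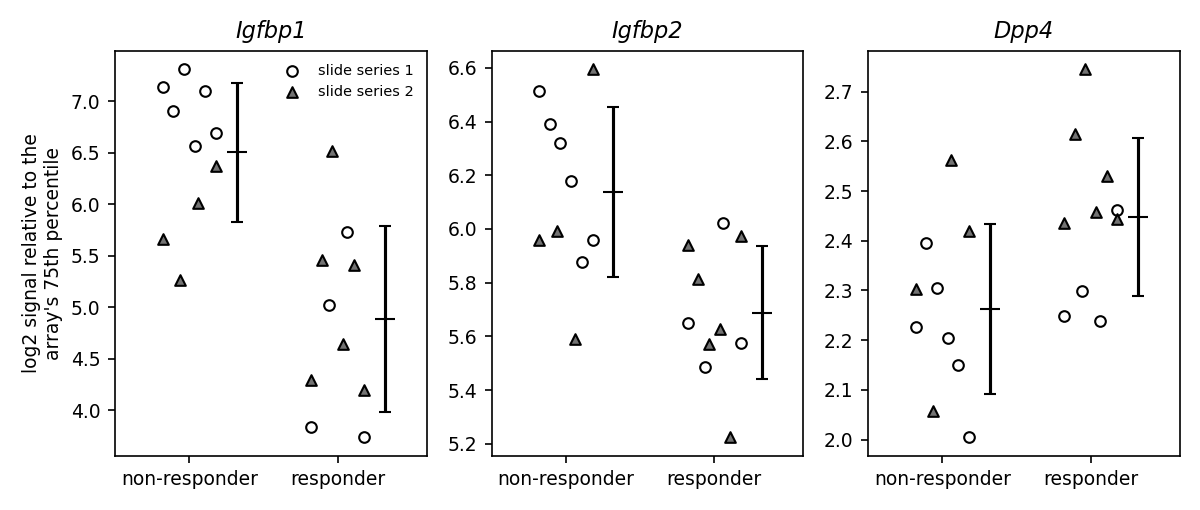
Signal of Igfbp1, Igfbp2 and Dpp4 on each of the 20 arrays, as log2 relative to the array's 75th percentile (vertical axis), by group (horizontal axis). Circles are arrays of slide series 1, triangles are arrays of series 2, the bar beside each group is its mean ± SD, and mean Igfbp1 was 4.88 in responders and 6.50 in non-responders.

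No gene passed the threshold over all genes. Of 17197 genes and unnamed probes tested with limma, 0 passed an adjusted p of 0.05, and the smallest adjusted p was 0.273. At an unadjusted p under 0.05 there were 1373, of which 731 were higher and 642 lower in responders, where 860 would be expected with no effect. Across all genes, the sign of the difference was the same in both slide series for 48.8%. On simulated data with the same arrays, the fit recovered 52.8% of genes changed by 0.5 on the log2 scale. It recovered 86.7% of those changed by 1 and 96.5% of those changed by 2. These sizes were mixed in each simulation, so the larger changes eased the adjusted threshold for genes changed by 0.5. The rates are therefore not the power of the real comparison, where 0 genes passed, and recovery of changes of 0.5 alone was not tested. The genes named next had the smallest unadjusted p with the same sign in both series, so their agreement between series follows from the rule. The counts of responders beyond the non-responder mean follow largely from it too. They are given as values and not as changes.

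Among the genes with higher values in responders, Fndc4, which encodes a secreted fibronectin-domain protein, differed by 0.31 (SE 0.05). Serpina12, the gene of the adipokine vaspin, differed by 0.73 (SE 0.16), and Lipc, which encodes hepatic lipase, by 0.30 (SE 0.07). The widest differences in this direction were those of Gna14, a G protein alpha subunit, at 1.22 (SE 0.26), and Tiam2, an exchange factor for Rac, at 1.08 (SE 0.24). Mmp15, a membrane-bound matrix metalloproteinase, differed by 0.46 (SE 0.12), and Tafa5 by 0.52 (SE 0.11) with signal well above background on 9 arrays of each group. Macroh2a1, a histone variant gene, differed by 0.21 (SE 0.05), Atxn7l1 by 0.59 (SE 0.14), Vps8 by 0.38 (SE 0.09), Tpgs2 by 0.32 (SE 0.07) and Ghdc by 0.29 (SE 0.07). Fndc4, Serpina12, Gna14, Tiam2, Atxn7l1, Vps8 and Macroh2a1 exceeded the non-responder mean of their series in all 10 responders, and the other genes in 9 of 10. Their adjusted p-values lay between 0.273 for Fndc4 and 0.490, and Macroh2a1 turned sign with normexp. In the first and second slide series, Tiam2 differed by 1.49 and 0.67, Mmp15 by 0.62 and 0.30, and Ghdc by 0.42 and 0.16. Serpina12 went the other way, at 0.54 and 0.92, and Lipc and Atxn7l1 slightly so.

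Among the genes with lower values in responders, Igfbp1, which encodes an insulin-repressed binding protein of insulin-like growth factors, differed by -1.56 (SE 0.35), a 2.95-fold lower signal. Its level was 4.88 ± 0.90 in responders and 6.50 ± 0.68 in non-responders (SD, n = 10 each), and 9 of 10 responders lay below the non-responder mean of their series. The Igfbp1 difference was -2.37 in the first slide series and -0.74 (SE 0.44) in the second, and whether these differ was not tested. Setd7, a lysine methyltransferase gene, differed by -0.44 (SE 0.08), and Acsl4, which activates arachidonic acid, by -0.42 (SE 0.10). Kyat3, a kynurenine aminotransferase gene, differed by -0.40 (SE 0.11), P2rx7, an ATP-gated channel gene, by -0.33 (SE 0.09), and Icosl, a T cell costimulatory ligand gene, by -0.35 (SE 0.09). Slc25a27, a mitochondrial carrier gene, differed by -0.64 (SE 0.17), Tmtc2 by -0.55 (SE 0.14), Golga5 by -0.26 (SE 0.07) and Zfp84 by -0.28 (SE 0.07), although the 3 probes of Zfp84 disagreed in sign. Foxc1, a forkhead factor gene, differed by -0.69 (SE 0.16) and Hhipl2 by -0.58 (SE 0.14), but Foxc1 was well above background on only 4 responder and 5 non-responder arrays and Hhipl2 on 5 and 4. Their adjusted p-values lay between 0.273 for Setd7 and 0.490. Foxc1, Hhipl2, Slc25a27 and Icosl turned sign with normexp, and Zfp84 in the authors' values. In the first and second slide series, Tmtc2 differed by -0.88 and -0.22, Kyat3 by -0.60 and -0.21, and Acsl4 by -0.58 and -0.26. In the same order, Setd7 gave -0.58 and -0.30 and Golga5 -0.36 and -0.16. The difference was larger in size in the second series for Icosl, at -0.51 against -0.19, and also for Foxc1 and P2rx7. The Igfbp1 probe lies on chromosome 11 from 7102442 to 7102501 in mm9.

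In the list of insulin, growth hormone and insulin-like growth factor genes, 11 of 28 measured members were higher and 17 lower in responders, with a mean difference of -0.13 (SE 0.06). The list as a whole did not pass camera, limma's test of a list against the other genes. Its adjusted p was 0.212 with the preset correlation and 0.682 with an estimated one. When adjusted over the list alone, 3 members passed, which were Igfbp1 at 0.00667, Igfbp2 at 0.0425 and Igfals, which encodes the acid-labile subunit of the circulating complex, at 0.0425, where 0 members passed over all genes. Igfals, named after its value was seen, was higher in responders by 0.37 (SE 0.12). The laboratories behind the series had studied Igfbp2 in these or related mice, so its count there is not independent evidence.

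Of the 30 gene lists fixed before the data were examined, camera with a preset inter-gene correlation of 0.01 called 12, with 9 lower and 3 higher in responders. This count carries little weight. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.682. The directional form of fry, a rotation test of each list alone for a shift in a shared direction, also called 0. The mixed form of fry, which counts changes in either direction, gave its smallest unadjusted p, 0.0013, for the insulin and growth hormone list. This p was not adjusted over the 30 lists. On simulated data in which no list was shifted, the preset test called a median of 12.5 of 30 lists, with a range of 3 to 16 over 20 simulations, and at least 12 in 11 of them. The estimated test called a list in 0 of these simulations. Whether it would find a real shift in lists with highly correlated members was not tested, so its 0 calls do not exclude one. The lists that the preset test called are therefore described by their values. The preset count was 21 with normexp, 7 with probes well above background on all arrays, 7 without responder 9, 6 within the first slide series and 5 with Adipoq as a covariate.

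**Figure D2:**
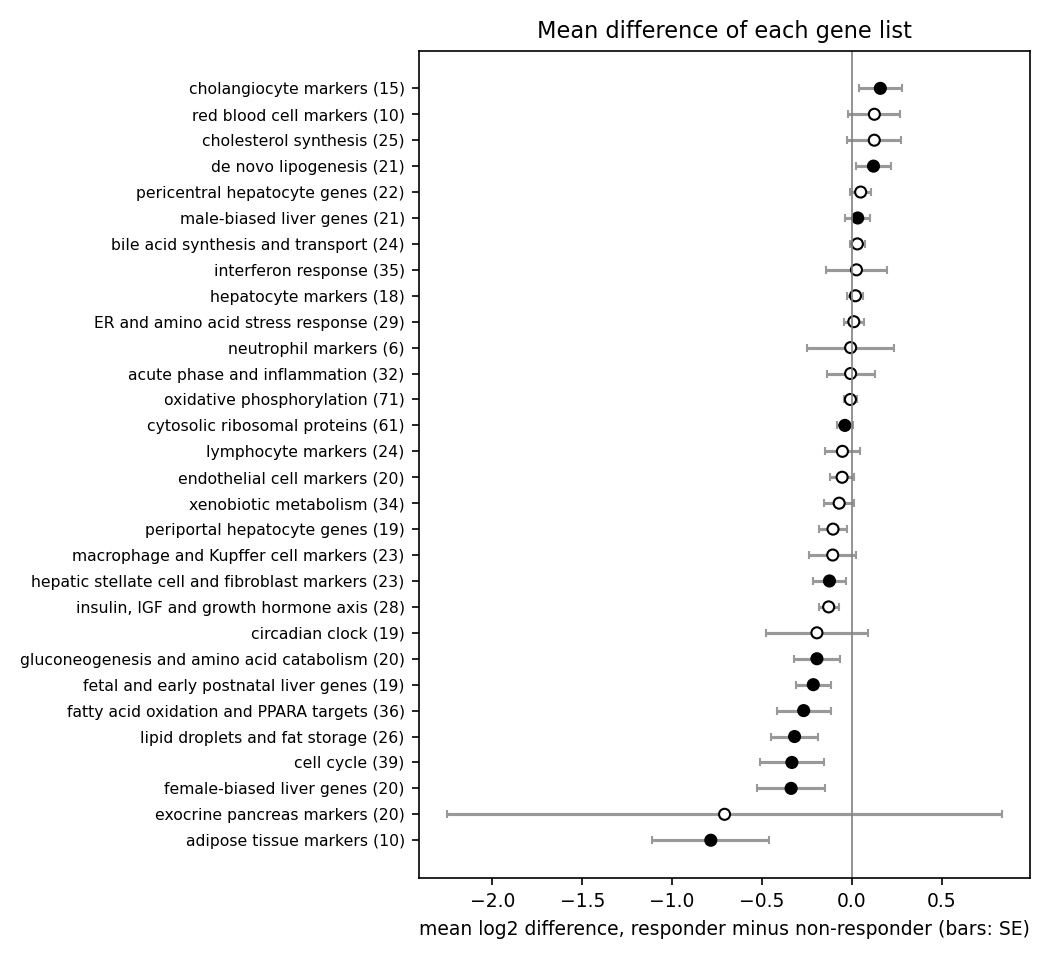
Mean log2 difference of each gene list (horizontal axis, responder minus non-responder, bars are the SE over arrays) for the 30 lists, with the number of measured members in brackets and the 12 lists called with the preset correlation filled, of which 0 were called with an estimated one. Adipose markers lie lowest at -0.79, and exocrine pancreas markers have the widest bar, with an SE of 1.54.

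Several of these lists concern fat and glucose metabolism. In the lipid droplet and fat storage list, 18 of 26 members were lower in responders, with a mean of -0.32 (SE 0.13) and an adjusted p = 0.682 with an estimated correlation. Cidec, a lipid droplet fusion protein gene, differed by -1.16 (SE 0.36), with -1.98 in the first slide series and -0.35 (SE 0.44) in the second, Fabp4 by -0.53 (SE 0.20), the lipase gene Lpl by -0.62 (SE 0.28) and Pnpla2, adipose triglyceride lipase, by -0.38 (SE 0.16). Of the fatty acid oxidation and PPARA target genes 28 of 36 were lower, with a mean of -0.27 (SE 0.15; adjusted p = 0.682 with an estimated correlation). The omega-hydroxylase genes Cyp4a14 and Cyp4a10 differed by -1.58 (SE 0.75) and -0.98 (SE 0.51), and the thioesterase genes Acot4 and Acot2 by -0.50 (SE 0.25) and -0.42 (SE 0.22). Gluconeogenesis and amino acid catabolism genes were lower in 15 of 20, with a mean of -0.19 (SE 0.13; adjusted p = 0.682 with an estimated correlation), which was -0.023 with 2 components of the clock genes as covariates. Got1 differed by -0.68 (SE 0.27), the serine dehydratase gene Sds by -0.56 (SE 0.27), the coactivator gene Ppargc1a by -0.46 (SE 0.20) and Pfkfb1 by -0.31 (SE 0.14). De novo lipogenesis genes were higher in 15 of 21, with a mean of 0.12 (SE 0.10; adjusted p = 0.682 with an estimated correlation), among them Pklr at 0.41 (SE 0.19), Acaca at 0.37 (SE 0.18) and the citrate carrier gene Slc25a1 at 0.21 (SE 0.08). No member of these 4 lists passed when adjusted over the list alone. In the first and second slide series the means were -0.57 and -0.067 for lipid droplets, -0.51 and -0.024 for PPARA targets, -0.33 and -0.055 for gluconeogenesis, and 0.11 and 0.13 for lipogenesis. The first and second series gave -1.75 and -0.21 for Cyp4a10 and -0.69 and -0.065 for Pnpla2. In the same order, Cyp4a14 gave -2.26 and -0.90 and Got1 -0.99 and -0.36. Lpl and Fabp4 went the other way, with -0.33 and -0.91 for Lpl and -0.44 and -0.63 for Fabp4. The lipogenesis mean turned to -0.21 with normexp, where Slc25a1 and Acot2 also turned sign.

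Markers of fat tissue were also lower in responders. Of 10 adipose markers 8 were lower, with a mean of -0.79 (SE 0.33; adjusted p = 0.682 with an estimated correlation). Plin1, the coat protein of adipocyte fat droplets, differed by -1.68 (SE 0.47), Adipoq, the adiponectin gene, by -1.37 (SE 0.58) and Cidea by -1.57 (SE 0.72). Plin1 alone passed when adjusted over the list alone, at 0.0200, but not over all genes in limma (adjusted p = 0.490). It was well above background on 3 responder and 8 non-responder arrays. The mean was -0.73 in the first slide series and -0.85 in the second. Some genes, such as Fabp4 and Cidea, belong to both the adipose and the lipid droplet list. Pancreatic enzyme genes varied between single livers far more than between the groups. Of 20 measured members 19 were lower in responders, but their mean ranged from -5.57 in non-responder 2 to 6.31 in responder 7. The group difference was -0.71 (SE 1.54), with a camera adjusted p of 0.218 at the preset correlation and 0.825 with an estimated one.

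**Figure D3:**
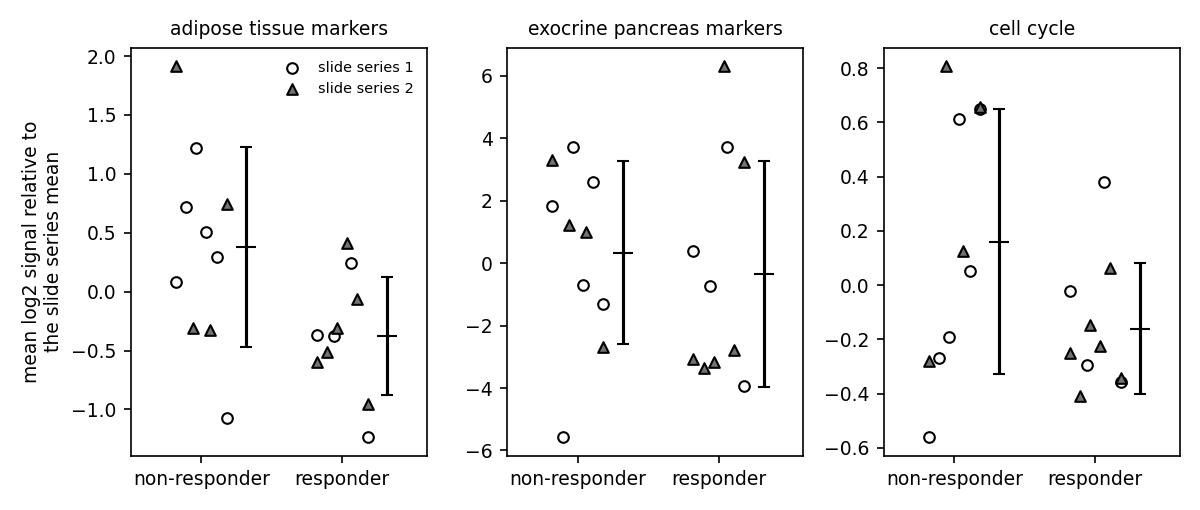
Mean log2 signal of the adipose, exocrine pancreas and cell cycle lists on each array, relative to the mean of its slide series (vertical axis), by group (horizontal axis), with circles for series 1, triangles for series 2 and bars for the group mean ± SD. Responder 7 stands highest in pancreatic enzyme genes at 6.31, and non-responder 7 highest in adipose markers at 1.91.

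Cell cycle genes were lower in responders in 32 of 39, with a mean of -0.33 (SE 0.18; adjusted p = 0.682 with an estimated correlation). The mean was -0.12 in the first slide series and -0.55 in the second. The mitotic genes Birc5, Ect2 and Tpx2 differed by -0.58 (SE 0.21), -0.73 (SE 0.28) and -0.82 (SE 0.32), and Kif11 by -0.57 (SE 0.21) with signal well above background on 6 responder and 7 non-responder arrays. With normexp Ect2, Tpx2 and Kif11 turned to 0.014, 0.10 and 0.32. The first and second slide series gave -0.26 and -0.91 for Birc5 and -0.23 and -0.92 for Kif11. Stellate cell and fibroblast markers were lower in 18 of 23, with a mean of -0.13 (SE 0.09; adjusted p = 0.682 with an estimated correlation), which was 0.027 with Adipoq as a covariate. Non-responder 7 was highest in both stellate markers, at 0.41, and adipose markers, at 1.91. The collagen genes Col1a1 and Col1a2 differed by -0.56 (SE 0.17) and -0.39 (SE 0.13), Vim by -0.40 (SE 0.12) and Lum by -0.24 (SE 0.11). Vim and Col1a1 passed when adjusted over the list alone, both at 0.0391. Neither passed over all genes in limma (adjusted p = 0.490 for Vim and 0.492 for Col1a1). Adjusted over the fetal list described next, Col1a1 stood at 0.0647 and did not pass. The first and second series gave -0.22 and -0.90 for Col1a1, -0.17 and -0.60 for Col1a2 and -0.030 and -0.45 for Lum. Fetal and early postnatal liver genes were lower in 15 of 19, with a mean of -0.22 (SE 0.10; adjusted p = 0.682 with an estimated correlation), but the leading members were the collagen genes Col1a1 and Col3a1, the latter at -0.34 (SE 0.15), with Tff3 at -0.38 (SE 0.18) and Slc38a4 at -0.36 (SE 0.20). Cholangiocyte markers were higher in 11 of 15, with a mean of 0.16 (SE 0.12; adjusted p = 0.682 with an estimated correlation), and the mean was 0.36 in the first slide series and -0.048 in the second. In the first and second slide series the means were -0.0018 and -0.25 for stellate markers and -0.076 and -0.35 for fetal genes, and Col3a1 differed by 0.057 in the first and -0.73 in the second. Of the cholangiocyte markers, Spp1 differed by 0.40 (SE 0.19), Cldn7 by 0.34 (SE 0.18), with 0.56 in the first series and 0.12 in the second, and Slc4a2 by 0.14 (SE 0.06), which turned sign with normexp.

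The livers were all male. Female-biased genes were lower in 17 of 20, with a mean of -0.34 (SE 0.19; adjusted p = 0.682 with an estimated correlation), and male-biased genes were higher in 16 of 21, with a mean of 0.032 (SE 0.07; adjusted p = 0.682 with an estimated correlation). Trim24 differed by -0.38 (SE 0.17) and Abcd2 by -0.44 (SE 0.28). Cyp4a10, at -0.98 (SE 0.51), belongs to both the female-biased and the PPARA target list, so these 2 lists are not independent. The complement gene C6 differed by 0.29 (SE 0.09), Keg1 by 0.32 (SE 0.11), the steroid enzyme gene Hsd3b5 by 0.42 (SE 0.18) and Ugt2b38 by 0.14 (SE 0.09). In the first and second slide series the means were -0.45 and -0.23 for female-biased genes and -0.023 and 0.087 for male-biased genes, and the male-biased mean was -0.43 with normexp. Abcd2 differed by 0.37 in the first series and -1.24 in the second, Hsd3b5 by 0.82 and 0.025, and Ugt2b38 by -0.020 and 0.30. Abcd2, C6, Keg1, Hsd3b5 and Ugt2b38 turned sign with normexp. Cytosolic ribosomal protein genes were lower in 49 of 61 by a mean of -0.039 (SE 0.04; adjusted p = 0.760 with an estimated correlation), or -0.0072 and -0.072 in the first and second series. Rps7 differed by -0.14 (SE 0.06), Rps23 by -0.12 (SE 0.06), Rpl14 by -0.13 (SE 0.08), with 0.0020 in the first series and -0.26 in the second, and Rps12 by -0.10 (SE 0.07), with -0.028 and -0.17 in the series and its 2 probes disagreeing in sign.

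The remaining lists did not pass even with the preset correlation. Mean differences were -0.11 (SE 0.13) for macrophage and Kupffer cell markers, -0.055 (SE 0.07) for endothelial markers, -0.053 (SE 0.10) for lymphocyte markers, -0.0074 (SE 0.24) for neutrophil markers and 0.12 (SE 0.14) for red blood cell markers. Hepatocyte markers differed by 0.020 (SE 0.04), pericentral hepatocyte genes by 0.048 (SE 0.06) and periportal genes by -0.11 (SE 0.08). Cholesterol synthesis genes differed by 0.12 (SE 0.15), bile acid genes by 0.030 (SE 0.04), xenobiotic metabolism genes by -0.071 (SE 0.08) and oxidative phosphorylation genes by -0.0085 (SE 0.03). Circadian clock genes differed by -0.19 (SE 0.28), acute phase genes by -0.0074 (SE 0.13), interferon response genes by 0.025 (SE 0.17) and stress response genes by 0.010 (SE 0.06). Of 19 clock genes 7 were higher and 12 lower, and members that move in opposite directions cancel in such a mean. The clock mean therefore does not show whether the groups differed in clock phase. The medians of the neutrophil and acute phase lists were 0.024 and 0.050, opposite in sign to their means. Some means turned sign between the first and second slide series. These were macrophage and Kupffer cell (0.021 and -0.23), lymphocyte (0.099 and -0.21) and neutrophil markers (0.26 and -0.27). Interferon response (0.15 and -0.10), acute phase (-0.11 and 0.095), stress response (-0.082 and 0.10) and oxidative phosphorylation genes (0.0021 and -0.019) also turned.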

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

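The tests on Igfbp1, adipose markers, Cidec and the cell cycle were all written after the values of these genes and the list means per array had been seen, and the tests on random splits were written before those splits were run. The test of slide series on Igfbp1 replaced, after both results were seen, one that asked whether the difference lay beyond 2 SE of 0 in each series, which had left slide series open because the second series did not. In the tests with covariates, the bound for arguing against a cause was that the larger part of the difference remained, by more than its SE.

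In 6 of 200 groups of 10 values, with the slide series removed, 1 array stood apart from the others of its group, where chance would give about 10. The values are differences from the group median. They are Slc38a4 at -1.37 in responder 7, Tpx2 at 1.29 in responder 3 and C6 at -0.61 in non-responder 10. Among list means they are ribosomal proteins at 0.18 in responder 3, endothelial markers at -0.45 in responder 9 and male-biased genes at -0.40 in non-responder 10.

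Chance was not excluded for the number of genes or of lists. Among 100 splits of the 20 arrays, the labelled one included, 9 gave at least the 1373 genes at an unadjusted p under 0.05, and the highest of the others gave 3527. For lists called with the preset correlation, 41 of 100 splits gave at least 12, and the highest of the others gave 18. The count of 0 genes past the adjusted threshold cannot be tested this way, since all 100 splits give at least 0. Of these splits 5 called any gene after adjustment, and 3 of the 5 called a single gene, so the number of such splits is no sign of a structure. The others called 164 and 713 genes, and the 713 may come from a structure of the samples other than the groups.

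Igfbp1 differed by -1.56 (SE 0.35) on the log2 scale between responders and non-responders, and did not pass adjustment over all genes. Clock state as the whole cause is argued against by a narrow margin, since the difference was -1.14 (SE 0.30) with 2 clock components as covariates, which held 93.5% of the clock list's variance. Slide series as the whole cause is argued against by the difference of -2.37 (SE 0.37) within the first series, where the series does not vary. Within the second series the difference was -0.74 (SE 0.44). The plain difference of -1.62 was -1.56 with the series as a term. Both groups were spread over both series, so that term could move the difference little. A stronger insulin or feeding signal in responders is a candidate explanation. In a chosen set of other insulin-repressed genes, 8 of 9 measured were lower, with a mean of -0.28 (SE 0.12). The exact two-sided permutation p of this mean within series was 0.0348. No gene of the set passed adjustment over all genes in limma (smallest adjusted p = 0.603, Ppargc1a). The mean was not tested with the clock components as covariates. Several of these genes were seen to be lower before the test, Angptl4, Cpt1a and Pdk4 are also PPARA targets, and the feeding state at sampling is not in the labels, so this remains a hypothesis.

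Adipose markers differed by a mean of -0.79 (SE 0.33) on the log2 scale, and Adipoq stood at -3.88 ± 1.44 in responders and -2.15 ± 1.74 in non-responders (SD, n = 10 each). Fat tissue carried over with some livers could account for the markers that follow Adipoq, since the median correlation of 9 markers with Adipoq across the 20 arrays, with group and series removed, was 0.691 (median rho 0.708), and 0.673 without the 2 arrays farthest from the median of Adipoq. By permutation with adjustment over the 9 markers, 7 passed, such as Plin1 (r = 0.809, permutation p = 3e-05, adjusted 6.75e-05; rho = 0.741, permutation p = 3e-04), but not Car3 (r = -0.327, permutation p = 0.158, adjusted 0.178; rho = -0.373, permutation p = 0.105) or Lipe (r = -0.019, permutation p = 0.937; rho = 0.051, permutation p = 0.832), and liver also expresses Car3, Lipe and Cd36. For Cidec, the difference was -1.06 (SE 0.44) with Adipoq as a covariate and -1.16 without, which passed the bound by a narrow margin. A single marker may not capture all carried-over tissue, so this does not exclude carryover as the whole cause. The Cidec difference was -1.98 in the first slide series and -0.35 (SE 0.44) in the second. Whether responder livers themselves expressed less of these genes stays open.

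Cell cycle genes differed by a mean of -0.33 (SE 0.18) on the log2 scale. Fewer macrophages and lymphocytes cannot be told apart from other causes, since the difference was -0.25 (SE 0.15) with both marker means as covariates, too close to the bound for a decision. Clock state is argued against, since the difference was -0.46 (SE 0.17) with the clock components as covariates. A difference in proliferation between responder and non-responder livers stays open and untested, as the list was not called with an estimated correlation.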

How the results depend on the processing

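The leave-one-out fits, the 3 arrays left out, the covariates and plain subtraction were chosen after seeing the data. In every setting run, 0 genes passed with limma, with 400 to 1923 at an unadjusted p under 0.05. The Igfbp2 difference stayed below 0 in every setting, from -0.98 with normexp to -0.34 within the second slide series. Single-gene permutation tests, not adjusted over genes, put the plain differences past 0.05 (Igfbp2 -0.45 with p = 0.00314, Dpp4 0.19 with p = 0.0226). Both genes came from earlier work on these or related mice, so these p-values are not independent evidence. Adjusted p-values over all genes in limma ranged from 0.241 to 0.811 for the Igfbp2 difference and from 0.338 to 0.945 for the Dpp4 difference. Without single arrays Igfbp2 ranged from -0.51 to -0.36, Dpp4 from 0.10 to 0.18 and the lists called from 7 to 14, with 7 without responder 9. The number of lists was 21 with normexp, 7 with probes above background on all arrays, 6 within the first slide series and 5 with Adipoq as a covariate. It was 0 with an estimated correlation and with the directional form of fry. The numbers in the titles did not meet the rule for pairing, which asks for every correlation above 0.1: same-numbered arrays correlated from -0.225 to 0.584 (mean 0.182), with 6 of 10 pairs above 0.1, and 6 of 20 arrays correlated best with their own number. A partial sharing stays open. The replicate block gave 0 genes, 16 lists, Igfbp2 -0.52 and Dpp4 0.13.

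The normexp setting failed on 6 arrays, 4 of them responders, where the fitted background mean lay more than 50 below 0, down to -3048. It turned Dpp4 to -0.15, Macroh2a1 -0.070, Foxc1 0.31, Hhipl2 0.32, Slc25a27 0.095, Icosl 0.14, Slc25a1 -0.27, Abcd2 0.16, Acot2 0.19, Slc4a2 -0.19, Kif11 0.32, Ect2 0.014, Tpx2 0.10, C6 -0.20, Keg1 -0.22, Hsd3b5 -0.069, Ugt2b38 -0.34 and the list means of lipogenesis to -0.21 and male-biased genes to -0.43. Plain subtraction with the same offset turned none of these (Igfbp2 -0.47, Dpp4 0.15, 12 lists). Elsewhere the cause was not tested. Zfp84 was 0.020 in the authors' values and Rps12 0.012 over all probes. In the first slide series Abcd2 was 0.37, Col3a1 0.057, Ugt2b38 -0.020 and Rpl14 0.0020. In the second series the cholangiocyte mean was -0.048, and the means of gluconeogenesis (-0.055), lipid droplets (-0.067) and PPARA targets (-0.024) kept their sign while the test's direction relative to other genes turned. Signal over background limits Plin1, Foxc1 and Hhipl2. The gluconeogenesis mean shrank to -0.023 with clock components, where the test's direction also turned, and the stellate mean turned to 0.027 with Adipoq as a covariate.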

Other observations

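The test of spread between the groups was written before its result was seen, and leaving out 3 arrays was chosen after the data were seen. The hypothesis that non-responder livers vary more than responder livers was not borne out: the median variance ratio over genes was 1.12, and 24 of 100 splits of the arrays gave a ratio at least as far from 1.

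Pancreatic enzyme genes moved together across the livers, with an estimated correlation of 0.949 between members, and this variation did not follow the groups. Adipose markers were highest in non-responder 7 at 1.91 and non-responder 3 at 1.22, relative to their slide series. Without responder 7 and these 2 non-responders, limma found 0 genes differing between responder and non-responder livers, with 1353 at an unadjusted p under 0.05, and camera called 9 lists with the preset correlation.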
